A study of Homo sapiens with 6 samples.

How the data were processed

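Thymidine glycol (Tg) is an oxidised form of thymidine, and the DNA glycosylases NTHL1 and NEIL1 cut such damaged bases out at the start of base excision repair. The sites were mapped by DPC-Seq in HEK293T, a human embryonic kidney cell line that carries the SV40 large T antigen. Per the labels' protocols, genomic DNA was cut enzymatically into short fragments and incubated with NTHL1 protein under reducing conditions, which ties the enzyme covalently to the DNA at the place of the removed base. The bound fragments were pulled down on nickel resin, separated by gel and membrane transfer, and made into libraries. The labels list 6 samples: 2 labelled libraries of wild-type cells, 2 labelled libraries of cells with NTHL1 and NEIL1 both disrupted (double knockout), and 2 input libraries, 1 of each genotype.

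The authors deposited 1 list of sites per genotype, with no header and no values per library. Each list was given its genotype because its name carries the same genotype word as the titles of the labelled libraries. Per the submitters' processing notes, Bowtie2, MACS2, bedtools and deepTools were used and the build was hg38; their versions, settings and roles are not given in the sources used here. How the 2 libraries of a genotype were combined, whether duplicate reads were removed, and which input served as control are likewise not given in the sources used here. Because each genotype has 1 list, there are no replicates, no spread between libraries, and no p-value for any comparison between the genotypes.

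The rows have the layout of a MACS2 narrow peak list without the name column. The deposited score of a site was 10 times its −log10 q, rounded down, in every row. The deposited fold enrichment of a site is a ratio of reads at its summit to the caller's background. The deposited −log10 p and −log10 q of a site are the caller's own, and the largest q was 0.0450 in the wild-type list and 0.0489 in the double-knockout list, so both lists hold sites with q below 0.05. These values are the authors' and were used only to describe, rank or filter sites within their own list, except where reads were recovered from them.

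Whole reads at the summit and the background were recovered from each pair of fold enrichment and −log10 p, taking the fold as reads plus 1 over background plus 1 and the p as the Poisson tail above the reads. A whole number of reads gave the deposited −log10 p within 0.001 at 100% of the 3688 wild-type and 9373 double-knockout sites. The lowest background in a list is the caller's genome-wide rate and moves with library depth. Per base pair of fragment length, taken as the narrowest site (243 bp and 256 bp), it was 1.61 times higher in the double-knockout list. The largest step of which most of the lower background values were whole multiples had the same ratio of 1.61. A control of the same size in both callings, or a control shared by both, gives this equality. Without division by fragment length the lowest backgrounds had a ratio of 1.69, and this ratio, of depth times fragment length, was the divisor of double-knockout reads wherever they were scaled or thinned. All fragments at a narrow site overlap its summit whatever their length, so the ratio of depth alone is another fair divisor, and the number of sites after thinning and the reads at shared sites were recomputed with it. Total reads per library are unknown. The strength of a shared site is the geometric mean of its wild-type and its scaled double-knockout reads. Reads at the summit of a site ranged from 6 to 405 in the wild-type list, median 13, and from 6 to 452 in the double-knockout list, median 17. Poisson intervals on such numbers are exact and cover counting error only, since reads copied in amplification are not independent molecules.

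Sites were set against 1000 random placements with a fixed seed, in which each site kept its chromosome and width. No genome sequence was used here, so the placement space ran from the outermost annotated gene or site of each chromosome to the other end, without gene-free stretches over 2 Mb, which stand in for assembly gaps. This removed 29 stretches of 206 Mb in all and left 2881 Mb, with 3561 wild-type and 9215 double-knockout sites inside it. A value was called above or below the placements when it lay outside their central 95% range. Placements move each site on its own, so this range does not cover the clustering of sites. Differences between the lists were given 95% intervals from 1000 bootstraps of 5 Mb genome blocks, which cover the clustering of sites along the genome and not variation between cultures. Placements for sites per chromosome ran over all chromosomes. Genes came from a RefSeq table of GRCh38.p14, which shares its primary coordinates with hg38 and holds 59792 genes, of which 20037 on the main chromosomes code for protein. A site was counted once by its midpoint: within 1 kb of either end of a protein-coding gene, in a protein-coding gene body, in another gene, or intergenic. The table used here gives no strand, exons or untranslated regions, so promoters, exons and introns were not told apart, although they had been chosen before. Windows of 1 Mb were ranked by the number of protein-coding gene midpoints in them into 5 density classes, with class 1 the poorest. Coordinates count from 1.

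The tests, the 13 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. That rule named NTHL1 and NEIL1. Per list it then named the 10 protein-coding genes of at least 20 kb with the most sites and the 10 with the most sites per 100 kb among genes with at least 3 sites. It further named up to 4 genes with the most sites from each gene list, and the 10 genes with the largest and the 10 with the smallest double-knockout minus wild-type number per 10000 sites. The 5 windows of 1 Mb with the most sites and the 5 sites with the highest score completed it. Some genes that the rule takes in are not reported here. Gene lists were also set against 10000 random lists of protein-coding genes drawn among the 200 nearest in length. Chosen after the data were seen were the recovery of reads, the thinning of double-knockout reads to the wild-type depth (100 draws) and the choice of its divisor. So were the share of sites near chromosome ends and the binomial intervals for genes that differed most. Alternatives chosen then left out sites of high background or NTHL1, kept gene-free stretches in the placements, widened gene edges or narrowed the end regions.

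The steps were tested on simulated data. Reads came back exactly at 100% of 1198 simulated sites. In 100 simulated lists with no preference, 5.75% of 400 shares in gene parts lay outside the placement range. Sites in these lists were placed independently, so this error rate does not cover clustered sites. Lists made with a true ratio of 1.63 at gene edges gave a mean of 1.62 and were called in 100% of 100 cases. Block intervals held 0 in 98.3% of 60 pairs without a difference. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.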

Results

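Genome-wide lists of Tg sites were compared between wild-type HEK293T cells and the isogenic line in which NTHL1 and NEIL1 were both disrupted. Each genotype was represented by 1 list for 2 labelled libraries, so no value below has a spread between replicates. The wild-type list held 3688 sites covering 1701 kb, with a median width of 380 bp and a median fold enrichment over background of 5.12 (highest 34.0). The double-knockout list held 9373 sites covering 4678 kb, with a median width of 409 bp and a median fold enrichment of 4.93 (highest 28.9). On chromosomes 1 to 22, X and Y lay 3621 wild-type and 9282 double-knockout sites.

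The first question was whether cells lacking the glycosylases carried more Tg sites. The double-knockout list had 2.54 times as many sites as the wild-type list. The double-knockout data were also 1.61 times deeper. When double-knockout reads at each site were thinned to the wild-type depth and both lists were counted above the median −log10 p of the wild-type list (8.46), 2393 double-knockout sites (range of draws 2321 to 2464) stood against 1856 wild-type sites, a ratio of 1.29 (1.25 to 1.33). Without thinning the ratio at that threshold was 2.89. At the 25th percentile of the wild-type −log10 p the thinned ratio was 1.43, at the 75th percentile 1.16 and at the lowest wild-type value 2.12. Thinned by the ratio of depth alone (1.61 in place of 1.69), the double-knockout list had 1.41 times as many sites at the median threshold (1.37 to 1.45), 1.55 times at the 25th percentile and 1.32 times at the 75th. At the 2719 wild-type sites shared with the other list, the median double-knockout to wild-type ratio of depth-scaled reads was 0.945 (95% block interval 0.933 to 0.960). Scaled by the ratio of depth alone it was 0.996 (0.983 to 1.012), so whether its interval excludes 1 depends on the scaling. By strength, the 1667 shared sites under 15 gave 0.936 (0.919 to 0.955) and the 971 from 15 to 30 gave 0.98 (0.952 to 1.005). The 81 of at least 30 gave 0.695 (0.668 to 0.777). By depth alone these were, in that order, 0.986 (0.968 to 1.006), 1.03 (1.003 to 1.06) and 0.732 (0.703 to 0.818).

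Most wild-type sites were found again in the double knockout. Of the wild-type sites, 75.4% shared at least 1 bp with a double-knockout site, against 0.382% of placements (range 0.197% to 0.590%). Of the double-knockout sites, 27.8% were shared, against 0.147% of placements (0.0760% to 0.228%). Sharing rose with the strength of a site, from 61.4% in the group with the highest q of 4 equal groups of the wild-type list to 91.9% in the group with the lowest q, and from 9.56% to 60.9% in the double-knockout list. Shared wild-type sites had a median fold enrichment of 5.26 against 4.87 for unshared sites, a difference of 0.386 (0.314 to 0.506). In the double-knockout list the medians were 5.73 and 4.72, a difference of 1.01 (0.899 to 1.099).

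**Figure D1:**
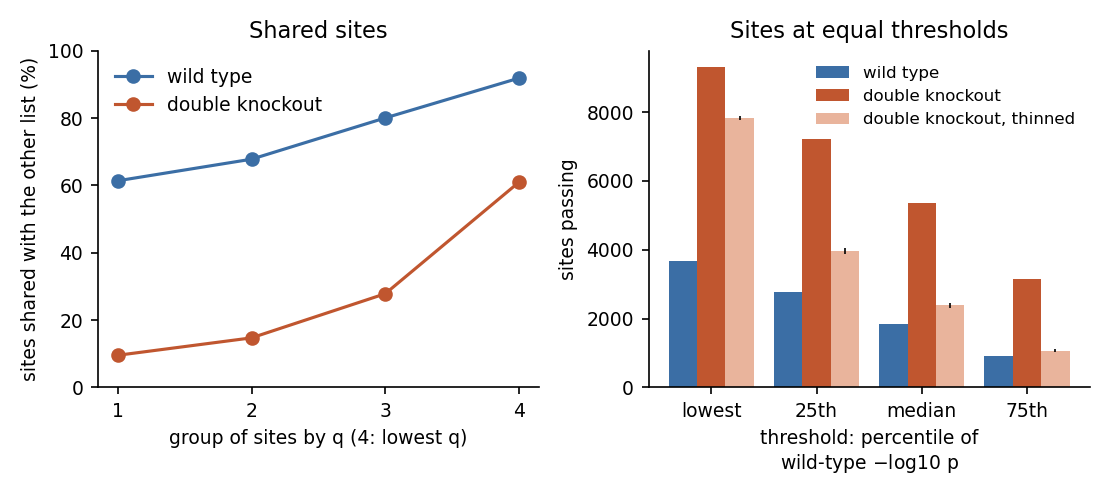
Left, the percentage of sites in each of 4 equal groups of a list by q (group 4 has the lowest q) that overlap a site of the other list, which reached 91.9% in wild type and 60.9% in the double knockout. Right, the number of sites above 4 thresholds taken from the wild-type −log10 p, for wild type, double knockout and double knockout thinned to the wild-type depth (mean and range of 100 draws); at the median threshold 1856, 5367 and 2393 sites passed.

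Of the disrupted genes, NTHL1 held 5 separate sites in each list and NEIL1 held none in either. Across the 8015 bp of NTHL1 (chromosome 16, 2039820 to 2047834) the wild-type sites had fold enrichments of 10.8, 16.9, 14.0, 31.9 and 17.4, in the order of their position, and the double-knockout sites 7.95, 12.6, 8.44, 20.2 and 13.1. The 10 kb on either side of the gene held no site. The site at 2045995 to 2046512 had the lowest q of the whole wild-type list (−log10 q 129, 110 reads, counting interval 90.4 to 133), and in the double knockout it ranked 2 (−log10 q 101, 108 reads, 88.6 to 130.4). Depth-scaled reads at the 5 sites were lower in the double knockout, with a median ratio of 0.648 and a range of 0.558 to 0.670, within the values of the 77 other shared sites with a strength of at least 30 (median 0.702). NTHL1 had more sites per 100 kb, 62.4, than any other protein-coding gene with at least 3 sites in either list. The lists mark DNA rather than transcripts, and since the kind of disruption is not stated in the sources used here, sites in NTHL1 do not check the genotype labels. NEIL1 (chromosome 15, 75347039 to 75357115) had no site within 10 kb either, and the rate of its chromosome would give only 0.0105 wild-type and 0.0311 double-knockout sites in the gene.

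**Figure D2:**
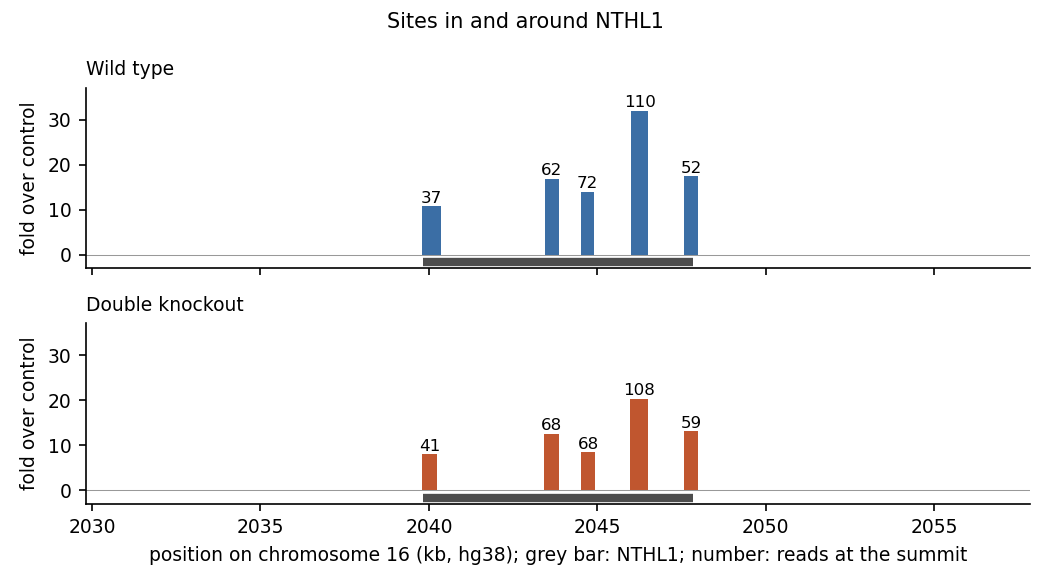
Sites in and within 10 kb of NTHL1 on chromosome 16 (position in kb, hg38) in wild type (top) and double knockout (bottom). Bar height is the authors' fold enrichment over control, bar width the site, the grey bar the gene, and the number the reads at the summit; 5 sites lie in the gene in each list and none in the flanks.

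The other sites with the highest scores were also found in both lists. A 635 bp site at chromosome 18, 80262752 to 80263386, outside any protein-coding gene, had a fold enrichment of 30.0 in wild type and 23.1 in the double knockout, where it ranked 1. A site at the tip of chromosome 5 (11373 to 11814) had folds of 25.4 and 18.9. A site in CTBP2, which encodes a transcriptional corepressor (chromosome 10, 125098501 to 125098948 in the double-knockout list), had folds of 34.0 in wild type and 28.9 in the double knockout. The sites on chromosome 16 from 46389537 to 46391024 and on chromosome 3 from 93470272 to 93470888 scored high on a raised background, 92.8 and 105 in wild type, with folds of only 4.28 and 3.82.

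Sites lay mainly in gene-rich parts of the genome in both genotypes. The windows richest in protein-coding genes (density class 5) held 36.5% of wild-type and 35.9% of double-knockout sites, 1.41 and 1.39 times the placements, and the poorest windows held 10.3% and 10.1%, 0.471 and 0.465 times the placements. Relative to single genes, the shares were close to those of the placements. Protein-coding genes with their edges held 48.3% of wild-type sites, which was inside the placement range (ratio 1.03), and 49.6% of double-knockout sites, slightly above it (1.06). Gene edges held 3.23% and 3.52% of sites, with ratios of 1.06 (inside the range) and 1.15 (above it). Intergenic sites made up 39.7% of the wild-type list (ratio 1.01, inside the range) and 38.0% of the double-knockout list (0.966, below it). The placement range does not cover the clustering of sites. Block intervals of the double-knockout shares held the placement mean for gene edges (2.82% to 4.27%, mean 3.06%) and intergenic sites (36.4% to 39.6%, mean 39.3%). The interval for any protein-coding gene did not (47.7% to 51.6%, mean 47.0%). Other annotated genes, which include long non-coding RNA genes and pseudogenes, were below the placements in both lists (0.874 and 0.908). That call was lost in both lists with placements kept within 1 Mb of each site (1.00 and 1.04). It was also lost with no gene-free stretch left out (0.922 and 0.963). In the main setting no difference between the genotypes in these parts or density classes had an interval that excluded 0. The double-knockout minus wild-type share was −1.73 percentage points for intergenic sites (−3.26 to 0.0162) and 1.29 points for any protein-coding gene (−0.469 to 2.94). The intervals did exclude 0 under 7 alternatives for intergenic sites (−4.08 to −1.92 points) and under 4 for any protein-coding gene (1.73 to 3.63 points), the thinned lists among them. Within the double-knockout list, sites without a wild-type partner were less often intergenic than shared ones (−2.58 points, −5.12 to −0.199). They lay more often in density class 3 (2.81 points, 0.493 to 5.18), and the intervals for the other parts and classes held 0. With placements kept within 1 Mb of each site, gene edges (0.809 and 0.893) and any protein-coding gene (0.931 and 0.949) fell below the placements and intergenic sites rose above them (1.0996 and 1.06) in both lists; density class 5 came to 0.985 and 0.996.

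**Figure D3:**
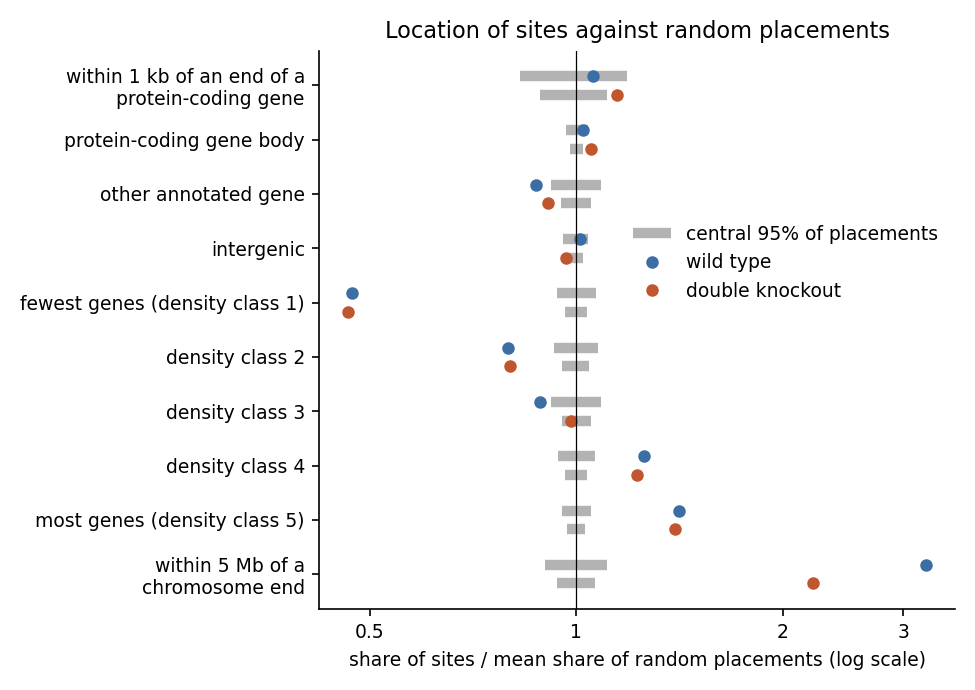
Ratio of the observed share of sites to the mean share of 1000 random placements (log scale) for gene parts, 5 density classes of 1 Mb windows ranked by gene number, and the 5 Mb at chromosome ends. Points are the 2 genotypes and grey bars the central 95% of placements; the points for density class 1 lie at 0.471 and 0.465 and those for chromosome ends at 3.23 and 2.21.

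Both lists were enriched towards the ends of chromosomes, and less so in the double knockout. Within 5 Mb of the outermost annotated gene or site lay 27.7% of wild-type sites, 3.23 times the placements, and 18.5% of double-knockout sites, 2.21 times the placements. These end regions close the annotated part of a chromosome and need not reach its tip, which was not checked. Placements within 1 Mb of a site stay near its end by construction, and against them the ratios were 1.008 and 1.007, inside the range. The difference was −9.14 percentage points (−11.6 to −6.72). Double-knockout sites without a wild-type partner lay near ends in 13.8% of cases and shared ones in 30.7%, a difference of −16.9 points (−21.3 to −12.1). Shared sites belong to the wild-type list by definition, so this largely restates the difference between the lists. They were also stronger (median −log10 q 9.30 against 5.07). Relative to the length of a chromosome's end regions, the share of sites near ends exceeded 1 on 23 of 23 chromosomes with at least 20 sites in the wild-type list and on 20 of 23 in the double-knockout list. After thinning, with both lists above the wild-type median p, the difference between the genotypes was −5.05 points.

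Chromosomes 19 and 22 carried the most sites for their length. On chromosome 19 lay 4.12 wild-type and 11.0 double-knockout sites per Mb, 3.33 and 3.46 times the genome-wide placements, and on chromosome 22 lay 3.86 and 8.30 per Mb (3.12 and 2.60 times). Chromosomes 1, 16, 17, 20 and 21 were also above the placements in both lists, with ratios from 1.26 to 1.84, but with 1 site per 100 kb chromosome 21 was inside the range in the double knockout (1.19). Chromosome 4 was low in both lists, with 0.585 and 1.36 sites per Mb (0.473 and 0.426 times), and chromosome 3 held 0.504 times the placements in wild type and 0.669 times in the double knockout. Chromosome Y had the lowest ratios, 0.0650 and 0.0378, with 2 wild-type and 3 double-knockout sites. The copy number of HEK293T chromosomes is uneven and was not corrected for. As a share of all sites, the double-knockout list was higher on chromosome 1 (11.97% against 10.50%), chromosome 3 (4.56% against 3.43%) and chromosome 11 (4.36% against 3.71%), the only chromosomes of 24 whose block interval of the difference excluded 0.

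**Figure D4:**
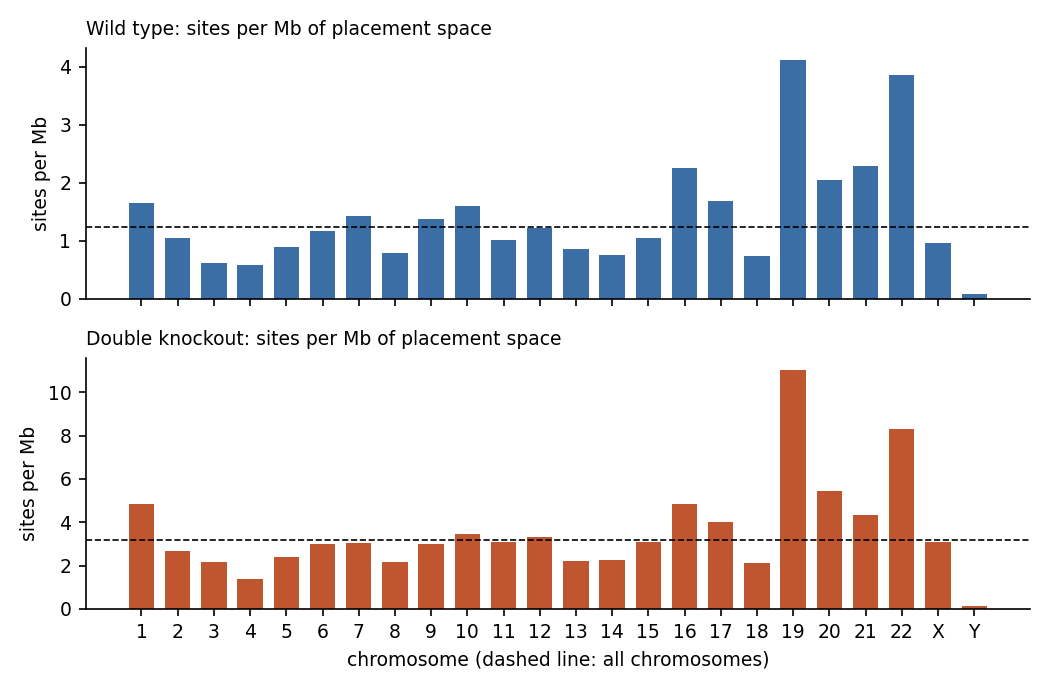
Sites per Mb of placement space on each chromosome in wild type (top) and double knockout (bottom); the dashed line is the rate over all chromosomes. Chromosome 19 has the tallest bar in both lists, at 4.12 and 11.0 sites per Mb.

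The genes with the most sites were long, and 5 genes were among the first 10 of both lists. The midpoint of the gene lay within 5 Mb of a chromosome end for 7 of the first 10 in wild type (PTPRN2, CDH4, COL5A1, GALNT9, GSE1, ADARB2 and RBFOX3) and for 4 of the first 10 in the double knockout (PTPRN2, CDH4, ADARB2 and RBFOX3). PTPRN2, which encodes a phosphatase-like protein of secretory vesicles (chromosome 7, 157539056 to 158587823), held 24 wild-type sites (counting interval 15.4 to 35.7) and 29 double-knockout sites (19.4 to 41.6), where the rate of its chromosome would give 1.504 and 3.213. CDH4, the gene of R-cadherin (chromosome 20, 61252261 to 61940617), held 15 (8.40 to 24.7) and 20 (12.2 to 30.9). CAMTA1, a calmodulin-binding transcription activator, held 8 and 14, COL5A1, a collagen chain, 8 and 9, ADARB2, a relative of the RNA-editing deaminases, 7 and 12, and RBFOX3, the splicing factor known as NeuN, 6 and 12. GALNT9 and GSE1 followed in wild type with 7 sites each, and DYSF, the membrane repair gene dysferlin, and COL22A1 with 6 each. In the double-knockout list FHOD3, a formin of muscle sarcomeres, SORCS2, a sortilin-family receptor, and the splicing factor gene RBFOX1 held 14 sites each, and CELF4 and the calcium channel gene CACNA1E held 11 each. RBFOX1 spans 2474 kb, and its 14 sites compare with 11.9 from the rate of its chromosome.

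By sites per 100 kb, NTHL1 was followed by MUC3A, a mucin gene, in wild type and by FXYD1 (50.7 per 100 kb) in the double knockout. MUC3A held 5 sites in wild type and 6 in the double knockout over 18.8 kb (26.6 and 31.9 per 100 kb), and MUC5AC, another mucin gene, held 4 and 7 (9.26 and 16.2 per 100 kb, ranks 8 and 9). ERFL, which overlaps ARHGEF1 on chromosome 19, held 5 and 4 sites (24.1 and 19.3 per 100 kb), and NUMBL, a regulator of Notch signalling, 3 and 4. CD5, SPPL2B, FOXN1 and ZNF511-PRAP1 completed the wild-type genes, at 9.14 to 11.8 per 100 kb. Of the densest double-knockout genes, FXYD1 and SLC38A5 held 3 sites each with no wild-type site, and ZYX, IFITM10 and LYPD8 held 3 or 4 with 1 wild-type site each. In all, 1179 of 20037 protein-coding genes (5.88%) held a wild-type site and 2797 (14.0%) a double-knockout site, and 1019 genes held both.

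The windows of 1 Mb with the most wild-type sites were at chromosome 12, 132000001 to 133000000, with 23 sites (30 in the double knockout) across EP400, GALNT9 and POLE, then at 157000001 and 158000001 on chromosome 7 over PTPRN2, with 19 sites each (22 and 26). Windows at 143000001 on chromosome 1 and 61000001 on chromosome 20, over CDH4 and TAF4, held 18 each (13 and 27). The double-knockout list led with 41 sites at chromosome 19, 50000001 to 51000000 (12 in wild type), a window with MYH14 and POLD1, and with 31 sites at 142000001 on chromosome 8 (13 in wild type), which holds TSNARE1, ADGRB1 and ARC. A window at 228000001 on chromosome 1, with WNT3A, held 27 double-knockout and 13 wild-type sites.

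Single genes that differed most between the lists were compared as sites per 10000 sites. FHOD3 had the largest difference, with 1 wild-type and 14 double-knockout sites (2.71 and 14.9 per 10000). It was followed by CSMD2 (1 and 11 sites), PTPRT, a receptor phosphatase gene (0 and 8), SORCS2 (3 and 14), COL5A3, COPG2 and RALGAPA2 (0 and 6 each), and DAB1 and THSD4 (1 and 8 each). In the other direction PTPRN2 had 65.1 wild-type and 30.9 double-knockout sites per 10000, and CDH4 40.7 and 21.3. COL5A1, COL22A1, GALNT9, NTM, the glutamate transporter gene SLC1A7, the glutamate receptor gene GRM4, CTNND2 and KNDC1 followed, with differences from −12.1 to −9.38 per 10000. Of all sites in a gene, the share from the wild-type list was set against the 28.2% that the sizes of the lists give. Its exact binomial interval excluded that value for PTPRN2 (24 of 53 sites, 45.3%, 31.6% to 59.6%) and SLC1A7 (5 of 7, 71.4%, 29.0% to 96.3%), and held it for the other 8 genes in that direction and for all 10 in the direction of FHOD3. The genes were picked for the size of this difference and sites within a gene are not independent, so these intervals are too narrow as a test. Sites per 10000 also depend on how deep each list reaches.

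Of the 13 gene lists, 1 lay above the placements and 2 below in each genotype, and 10 were inside the range. Base excision repair genes held 6 wild-type sites, 5.37 times the placements, and 12 double-knockout sites, 4.11 times, with NTHL1 giving 5 in each. OGG1, the glycosylase for 8-oxoguanine, held 1 and 3 sites, SMUG1, a uracil glycosylase, 0 and 2, and APEX2 0 and 1. Without NTHL1 the ratios were 0.912 and 2.42, and with 1 site per 100 kb they were 2.54 and 2.91; in either setting neither list was above the placements any longer. Long genes at common fragile sites held 44 and 98 sites, 0.722 and 0.643 times the placements. These included RBFOX1 and DAB1 (1 and 8), and PTPRN2 alone gave 24 and 29. In wild type the block interval of the share (0.303% to 2.77%) held the placement mean of 1.71%. The double-knockout interval (0.471% to 1.91%) likewise held its mean of 1.65%. The deficit was therefore not beyond the clustering of sites. The wild-type ratio was inside the placement range under 5 alternatives (0.756 to 0.991), among them placements within 1 Mb and the thinned lists. ZNF genes on chromosome 19, which encode zinc finger proteins in clusters, held 7 and 33 sites, 0.246 and 0.432 times the placements. Placements keep the chromosome, so these ratios are relative to chromosome 19, which itself held 3.33 and 3.46 times the genome-wide placements. ZNF536 held 0 and 5 and ZNF331 2 and 2. By the share of genes with a site, each of these 3 lists was inside the range of random lists matched on gene length. A site was held by 8% and 20% of the 25 base excision repair genes (percentiles 81.2 and 92.6), by 30.6% and 63.9% of the long genes (random mean 30.0% and 55.7%), and by 2.5% and 10.8% of the ZNF genes (4.602% and 11.16%).

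The lists inside the range were small in number of sites. Antioxidant defence genes held 2 and 6 sites (1.75 and 2.17 times the placements), with 2 each in SOD2, the mitochondrial superoxide dismutase, and 0 and 2 in GCLC. Genes of nucleotide excision and double-strand break repair held 2 and 8 (0.635 and 0.962), among them ERCC6 with 1 and 2 and PRKDC with 0 and 2. Tumour suppressors and oncogenes held 7 and 13 (1.74 and 1.41), of which EGFR held 5 in each list and ALK 2 and 4. Housekeeping genes held 1 site in each list, in POLR2A, the gene of the largest RNA polymerase II subunit. Olfactory receptor genes held 2 and 9 (0.483 and 0.780, and below the range at 0.233 and 0.424 when 5 kb on either side were counted), HOX genes 0 and 1, ribosomal protein genes 0 and 1, in RPS14, and keratins with their associated proteins 0 and 3. Replication-dependent histone genes and clustered protocadherins held none in either list, where placements gave at most 0.452 and 1.14 sites on average. By the share of genes with a site, the 53 protocadherin genes (0%) were below the range of random lists in both genotypes. Random lists gave 7.98% (1.89% to 15.1%) in wild type and 19.5% (9.43% to 30.2%) in the double knockout. These genes share much of their DNA, so that share counts few places many times.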

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

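The share of sites near chromosome ends was examined only after the data were seen, and the 3 tests of it were chosen before their own results were known. For gene density, the bound first set for excluding the explanation (a ratio over 1.5 in every class) was not met, and the comparison with the value that the explanation itself needs was chosen after the results were seen.

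Sites near chromosome ends made up a smaller share of the double-knockout list than of the wild-type list, by −9.14 percentage points, with a block interval that excluded 0. In every class of gene density the sites of both lists lay near ends more often than placements did. The lowest ratio was 1.42 (1.302 against the upper end of the placements), above the 1.2 allowed if gene-dense windows at the ends were the cause. The bound first set was not met, and placements move each site on its own. The ratio was highest in the gene-poorest class, at 5.97 in wild type and 3.86 in the double knockout. These values argue against gene-dense windows as the whole source of the enrichment, although a part in it is not excluded. Clusters of sites within 100 kb do not account for all of the enrichment, with a ratio of 1.84 in the double-knockout list when 1 site per 100 kb was kept. Clusters over longer stretches were not tested this way. The control background at sites near the ends was at most 1.196 times that at other sites, but it is known only at listed sites, over which they were called, so it decides nothing about the control as a source. Base composition, repeats and copy number of the end regions stay open too, as none was tested, and so does the genotype as the source of the difference, which may in part follow the depth of the lists, since it was −5.05 points after thinning.

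ZNF genes on chromosome 19 held a larger share of the double-knockout sites, by 0.162 percentage points (0.0218 to 0.331). Both lists had fewer sites there than placements, which keep the site-rich chromosome 19. Of the 24 gene parts, density classes, end regions and gene lists compared between the genotypes, these ZNF genes and the chromosome ends were the 2 whose intervals excluded 0. Among 24 chromosomes, the double-knockout share was higher by 1.47 points on chromosome 1 (0.347 to 2.58), by 1.13 points on chromosome 3 (0.335 to 1.95) and by 0.656 points on chromosome 11 (0.00832 to 1.38). The intervals were not adjusted for the number of comparisons, and lists with no site in either genotype could not exclude 0. Alternate, unplaced and unlocalised sequences held 57 wild-type and 82 double-knockout sites, on 21 and 31 contigs. These sites entered the numbers of sites, the thinning and the groups by q, but no comparison by location. The strongest of them, on alternate sequences, had fold enrichments of 23.6 and 23.1.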

How the results depend on the processing

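Chosen only after the data were seen were the thinning of double-knockout reads and its divisor, and leaving out sites of high background or NTHL1. So were keeping gene-free stretches in the placements, wider gene edges and the 2 Mb end regions. The other alternatives were chosen before. Of 557 recomputed values, 92 equalled the main value, among them those that the setting could not move. A value inside the range could change direction and still keep its side of the threshold. Wild-type gene bodies did so, from 1.02 to 0.990 in the stricter part of the list by q. Of the other 465 values, 400 kept their side of the threshold. Among these others the overlap of the lists stayed above placements in 21 of 21 (ratios 67.3 to 407), as did the deficit of density class 1 in 19 of 19 (0.225 to 0.866), the higher fold of shared sites in 12 of 12 (0.205 to 1.18) and the lower double-knockout share near chromosome ends in 9 of 9 (−9.19 to −3.56). Placements within 1 Mb keep a site near its own window, which can draw ratios towards 1. With them density class 5 came to 0.985 in wild type and 0.996 in the double knockout, and chromosome ends to 1.008 and 1.007. All of these were inside the range, but density class 1 stayed below it (0.852 and 0.866), so the construction alone does not set a class to 1. These placements also turned gene edges (0.809 and 0.893), gene bodies (0.941 and 0.954), any protein-coding gene (0.931 and 0.949), other genes (1.00 and 1.04) and double-knockout intergenic sites (1.06). Wild-type intergenic sites rose above the range (1.0996). The gene part results depend on this choice, and the cause was not tested. Leaving out no gene-free stretch, which adds gene-poor space to the placements, turned wild-type intergenic sites to 0.941, raised any protein-coding gene in wild type to 1.08, and made the differences of the lists 1.73 points there and −2.28 points for intergenic sites, with intervals that excluded 0; other genes lost their calls (0.922 and 0.963). In the part of each list with the lowest q (1844 and 4686 sites) wild-type intergenic sites reached 1.07, double-knockout ones lost their call (0.965), and the differences were 3.63 points for any protein-coding gene and −3.90 points for intergenic sites. After thinning (1856 and 2366 sites, ratio 1.27 in the draw used) wild-type intergenic sites reached 1.06, double-knockout gene edges (1.13) and intergenic sites (0.960) lost their calls, and the differences were 3.37 points for any protein-coding gene, −4.08 for intergenic sites, −1.61 for density class 1 and, turned, 2.45 for density class 5. Thinning by the ratio of depth alone left 2623 double-knockout sites (ratio 1.41). With that scaling the median ratio of reads at shared sites was 0.996, with an interval (0.983 to 1.012) that held 1. With the double-knockout list reduced to the wild-type number of sites the differences were 0.609 points for gene edges, 1.93 for any protein-coding gene, −2.09 for intergenic sites and −1.14 for density class 1. On chromosomes 1 to 22, double-knockout gene edges (1.104) and intergenic sites (0.977) lost their calls and the intergenic difference was −1.92 points; counting any base in a part gave 0.979 and −1.97 points. Gene edges of 2 kb gave 1.25 in wild type and an intergenic difference of −1.97 points, leaving out high background gave 1.04 for any protein-coding gene in wild type, and 1 site per 100 kb gave a density class 5 difference of −2.72 points. Base excision repair lost its call in both lists without NTHL1 (0.912 and 2.42) and with 1 site per 100 kb (2.54 and 2.91). Also lost were the wild-type calls of long genes at fragile sites under 5 alternatives (0.756 to 0.991) and that of chromosome 21 in the double knockout with 1 site per 100 kb (1.19). Beyond the constructions named, the cause of these changes was not tested. No paired analysis was possible because each genotype has 1 list with no values per replicate, so leaving out a replicate was not run either. Also not run, for want of a genome sequence, strand or exons here, were GC-matched placements, sites over repeats left out, base composition, repeats, and promoters of 2 kb upstream to 500 bp downstream. Depth limits which weak sites are listed, but its part in the low sharing of the weakest of 4 groups of the double-knockout list (9.56%) was not separated from sites present in that genotype alone.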

Other observations

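Mitochondrial DNA carried sites over most of its length in both genotypes. Its 16569 bp held 10 wild-type sites that covered 64.4% and 9 double-knockout sites that covered 65.6%. In each list 12 of the 13 protein genes had a site, the exception being ND3, which encodes a subunit of respiratory complex I, together with both ribosomal RNA genes and 9 of the 22 transfer RNA genes. The enrichment was modest on a high background: folds ran from 3.16 to 4.39 in wild type over backgrounds of 47.8 to 75.7 reads, and from 2.33 to 3.31 in the double knockout over 80.8 to 126. Depth there differs from the nuclear genome because a cell has many mitochondrial genomes, and the values of the lists were not set against each other.

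Of the tests in the next paragraphs, the comparison with deeper sequencing was chosen before its result was known, and the others (enrichment at shared sites, a construct, extra copies, the share of sites at the lowest p) only after. For NTHL1, wild-type DNA mixed into the double-knockout libraries was tried first and replaced by extra copies once the median depth-scaled ratio of 0.648 at its sites was known, which was above the 0.5 that such mixing was taken to need.

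The double-knockout list held more sites than the wild-type list, and a stronger pull-down of labelled DNA in its libraries would raise the reads at sites seen in both lists. The depth-scaled median there was 0.945, or 0.996 with the ratio of depth alone, and picking sites by the shallower list can lower it. The 81 strongest shared sites lay below 1 with either divisor (0.695 and 0.732). The 1667 of strength under 15 lay at 0.936 (0.919 to 0.955), or 0.986 (0.968 to 1.006) with the ratio of depth alone. Only the 971 of strength 15 to 30 had an interval above 1, and only with the ratio of depth alone (1.03, 1.003 to 1.06). A slightly stronger pull-down therefore stays open. Deeper sequencing may account for much of the excess, which shrank from 2.89 to 1.29 times at the median wild-type p (1.41 with the ratio of depth alone), but the data do not settle whether for all of it, and a higher load of Tg in cells without NTHL1 and NEIL1 stays open beside it. The bound set in advance, over 1.5 times at the lowest wild-type p, was passed with 2.12 but does not compare like with like: the double-knockout list as deposited had only 5.04% of its sites between the lowest and the 5th percentile of the wild-type p, close to the 5.02% of the wild-type list, while after thinning it had 22.02%, which no caller had filtered. At the 25th percentile the bound was passed in every draw with the ratio of depth alone, 1.55 (1.52 to 1.59), but not with the main divisor, 1.43 (1.40 to 1.46), so the verdict there depends on the divisor.

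NTHL1, the enzyme that was added to label the DNA and a gene disrupted in the double knockout, held 5 strong, separate sites in both lists. Extra chromosomal copies of the region would be in the control too, but the median fold over the control at these sites was at least 2.55 times the median of all sites in a list. A candidate explanation is DNA of an NTHL1 coding construct in the libraries, carried over from making the enzyme. That the gene ranked 1 by sites per 100 kb, with no site in the flanks, was known when this was raised and does not test it. Whether the 5 sites match exons was not tested, since exon positions were not used here. A local excess of Tg in NTHL1 in both genotypes stays open as the biological alternative.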
